A study of Rattus norvegicus with 12 samples.

How the data were processed

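Poly(A) RNA was measured in 12 libraries of fibro-adipogenic progenitors, the mesenchymal cells of skeletal muscle that can give rise to fat cells and to fibroblasts. The cells came from the soleus muscle of rats (Rattus norvegicus) and were grown as primary cultures, per the labels. The labels give 6 groups of 2 libraries: cells of control rats, of rats after 7 days of hindlimb suspension and of rats after 14 days of it, each at day 0 and at day 3 of adipogenic induction. In hindlimb suspension the hind legs of the animal bear no weight, so that the soleus is unloaded. The induction medium held insulin, dexamethasone and 3-isobutyl-1-methylxanthine, per the labels' protocols. Libraries were made with a stranded mRNA kit (TruSeq) and sequenced on a NextSeq 2000 with reads of 51 bp, per the labels.

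The deposited table holds raw counts for 32622 Ensembl rat gene identifiers in 12 columns, whose names match the labels of the 12 libraries, and it holds no other column of values. FastQC 0.11.9, STAR 2.7, featureCounts 1.6.4, DESeq2 and the rat genome build Rnor_6.0 are named per the submitters' processing notes. What each tool was used for, its settings, the strand setting and the annotation release are not given in the sources used here. Overlapping genes and near-identical copies of a gene can share reads, and how such reads were counted is not given in the sources used here either. The files do not pair the identifiers with gene names: 0 of the 32622 identifiers matched the table of rat gene names that was used.

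This decided what could be done. Before the data were examined, 34 lists of gene symbols (pathways and markers of cell types) and a rule for the genes to name had been fixed, together with camera and fry tests of the lists. None of these list tests was run, because they need symbols, and no result below speaks of a pathway or a cell type by its genes. The rule was to name, in each comparison, the 5 genes with the largest fitted rise and the 5 with the largest fall among those past the FDR threshold whose groups did not overlap, with a mean of at least 5 CPM in the higher group and a proper gene symbol, along with fixed genes and list members. Without its condition on the symbol, its ranking was used to choose 4 identifiers: the top rise and the top fall of control cells from day 0 to day 3, and those of day 3 cells after 14 days of unloading against control. The ranking rests on fitted fold changes, which have no bound for a gene with 0 reads in a group.

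Total counts per library ranged from 15105521 to 21484885. Genes were kept by filterByExpr of edgeR (4.0.16 in R 4.3.3), which left 13215, and libraries were scaled by TMM. The quasi-likelihood test of edgeR (glmQLFit, glmQLFTest) was run in 1 fit of 6 group means to all 12 libraries, with 6 residual degrees of freedom, 9 two-sided comparisons of groups and 2 interactions, each the difference between the day 3 minus day 0 change of unloaded cells and that of control cells. The Benjamini-Hochberg FDR was 0.05 within each comparison, and each adjusted p below comes from this test. The overlap of the 7-day and 14-day changes was counted in a fit of the 6 libraries of 1 day. A level is given as CPM on TMM-scaled libraries, as mean ± SD over 2 libraries. A group with 0 reads in both libraries allows up to 3 counts over the group, or 0.0749 to 0.0931 CPM, and folds against such a group were computed against that floor. If both reads of a pair were counted, the floor would be 3 pairs. These limits cover counting error only. Principal components and replicate correlations used log2 CPM with a prior count of 2.

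The labels number the replicates but do not say that they came from separate animals or cultures. The p-values therefore measure the spread between these libraries, which may be technical, and with 2 libraries per group no outlier can be told. The replicates of each group differed by more than the sampling noise of single reads: the chi-square of their counts, divided by its degrees of freedom, was between 2.69 and 7.36 over genes with at least 20 reads. The mean over genes with 20 to 99 reads was 2.13 to 2.34, and over the genes with the most reads 5.99 to 75.2. Counting both reads of a pair would raise these values without any difference between the replicates. The replicates were used as 2 libraries each.

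In each library, 68.3% to 70.6% of the counts from 1 to 20 were even numbers. In the first control library at day 0, for example, 441 genes had a count of 1 and 921 a count of 2. The counting error of a value is then larger than that of as many single reads, and the counts of changed genes, the 4 named genes, the correlations of the responses, the overlap and the main values of the groups of 44 and 69 genes were recomputed on halved counts.

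Groups of genes were made from the calls, since no list could be used; their definitions were chosen after the data had been seen. A gene counted as switched on in a treatment if it rose from day 0 to day 3, reached at least 5 CPM at day 3 and was at least 32-fold above its day 0 level or floor. A gene counted as high or low at day 0 if it differed from control by at least 4-fold and reached at least 5 CPM in the higher group. Medians over such a group use ratios of mean CPM with each group no lower than its floor.

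The procedure was tested on simulated counts for the 13215 genes, 200 of them changed. Rises and falls were about balanced, and all other genes were equal in all groups. The real comparisons changed far more genes, 4132 for 14 days against control at day 3 and 6960 for control cells at day 3 against day 0. The shares below may therefore not hold for them. For 14 days of unloading against control at day 3, it recovered 62.7% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 92.4% of those changed 4-fold, and 3.70% of its calls were false. With reads simulated in pairs, those shares were 52.2%, 83.6% and 95.5%, with 1.91% false calls. For control cells at day 3 against day 0 it recovered 47.8%, 77.6% and 95.5% with single reads and 50.7%, 80.6% and 87.9% with reads in pairs. The alternatives fixed before the data were examined were median-ratio size factors, DESeq2 (1.42.0), limma voom (3.58.1), no filter, a filter of at least 1 CPM in at least 4 libraries, fits of only the groups compared, replicate blocks, an FDR of 0.1 for the overlap, genes with a mean of at least 10 CPM for the correlations, and leaving out each library in turn. Halved counts, scaling to the total count, calls of the joint fit for the overlap and the rebuilding of the groups of 44 and 69 genes under the alternatives were added after the data had been seen. Leaving out mitochondrially encoded genes before scaling was planned and was not run, because those genes could not be told without names.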

Results

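RNA was sequenced from soleus fibro-adipogenic progenitors of control rats and of rats after 7 or 14 days of hindlimb suspension (unloading), at day 0 and day 3 of adipogenic induction, with 2 libraries in each of the 6 groups. Libraries held between 15105521 counts (control at day 3, replicate 1) and 21484885 (14 days, day 0, replicate 2), and between 14930 and 15275 genes had at least 1 read. The same gene was the most abundant in all 12 libraries, with 2.10% to 4.09% of the counts. Replicates correlated over genes at r = 0.988 to 0.991 in log2 CPM, and the biological coefficient of variation of the fit was 5.66%. The first principal component held 60.8% of the variance and separated day 3 from day 0. The second, with 11.97%, set the 7-day libraries against the control libraries at both days, with the 14-day libraries between them. The third, with 9.02%, set the 14-day libraries (15.5 to 38.0) apart from the control and 7-day libraries (-21.1 to 3.09).

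**Figure D1:**
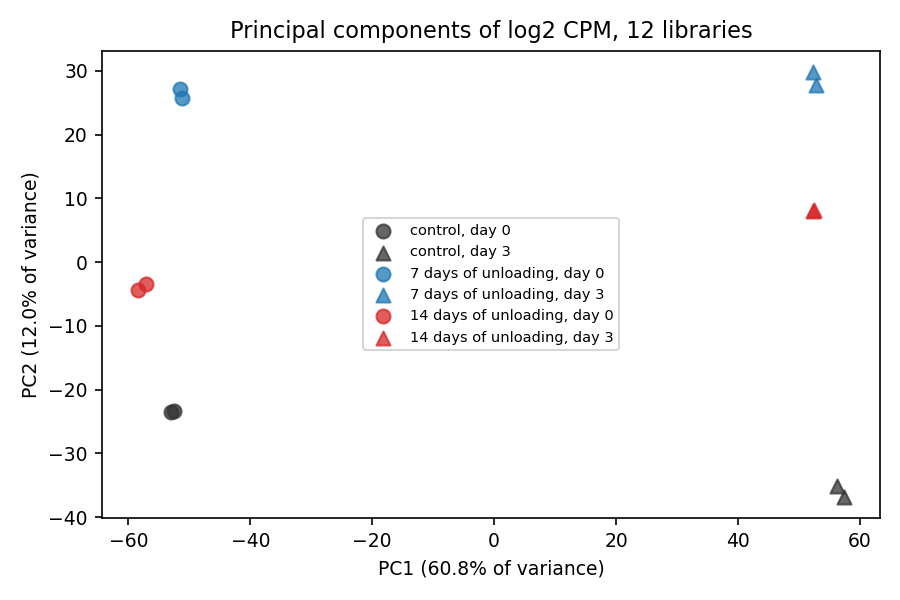
Principal components of log2 CPM for the 12 libraries: PC1 (60.8% of the variance) on the horizontal axis and PC2 (11.97%) on the vertical axis, each point a library, circles day 0 and triangles day 3. Both libraries of a group lie close together, the days separate along PC1, and along PC2 the 7-day libraries lie at the top and the control libraries at the bottom.

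The first question was how control cells responded to 3 days of induction. No group was kept to day 3 without induction, so a change from day 0 to day 3 also includes the added time in culture. The response to induction means this whole change here and below. About as many genes rose as fell: 3414 rose and 3546 fell of 13215 tested, and 921 of the rises and 1331 of the falls were at least 2-fold. A group of 44 genes was switched on, rising at least 32-fold to at least 5 CPM, with a median 96.4-fold rise; 14 of them were at or under the floor at day 0. Together these 44 genes took 0.00601% ± 0.0000608 of the counts at day 0 and 1.05% ± 0.000337 at day 3 (SD, n = 2). The largest rise was that of ENSRNOG00000028616, which had 0 reads at day 0, allowing up to 0.0813 CPM, and 131 ± 6.71 CPM at day 3 (SD, n = 2), at least 1615-fold higher if each count is a read of its own and at least 808-fold if reads were counted in pairs (adjusted p = 3.00e-28). ENSRNOG00000003669 fell from 8.23 ± 0.992 CPM, or 303 reads, to 1 read in both libraries together (adjusted p = 5.14e-14), too few for a fold to be given.

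Cells of unloaded rats responded to induction with similar numbers of changed genes. After 7 days of unloading, 3275 genes rose and 3552 fell between day 0 and day 3, and after 14 days 3662 rose and 3714 fell. In all 3 treatments 1992 genes rose and 2306 fell, 509 and 778 of them at least 2-fold in each, while 339 genes rose in at least 1 treatment and fell in another. Over 13215 genes the log2 changes of control and 7-day cells correlated at r = 0.79 (Spearman 0.76), those of control and 14-day cells at 0.72 (0.70) and those of 7-day and 14-day cells at 0.81 (0.80). These 3 responses share no library, and genes are not independent replicates. Without a filter on low counts the correlations were 0.42, 0.41 and 0.44.

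The responses also differed, by the test of the difference itself. The day 3 minus day 0 change differed from that of control cells in 1371 genes after 7 days of unloading, 621 of them more positive and 750 more negative, and in 2900 genes after 14 days, 1457 and 1443. Of the 1371, 337 changed in the same direction by less, 287 in the same direction by more, 119 in opposite directions, 324 passed the threshold in control cells alone and 297 in the unloaded cells alone. Of the 2900, these numbers were 445, 717, 299, 630 and 774. Both differences passed the threshold with the same sign in 1029 genes and with opposite signs in 16. Independent lists of these sizes would share 150.4 with the same sign and 150.5 with opposite signs. The correlation of the differences over genes was 0.63 with a covariance of 0.469, where 20 simulations with no difference in response and the same controls gave means of 0.52 and 0.117. These simulations held no real difference of the control response from the others, so they do not show what such a difference would give. The control libraries cannot be split, so part or all of the overlap may come from them. With scaling to the total count, 35.7% of the 7-day differences were positive, against 45.3% with TMM, and 36.9% of the 14-day differences, against 50.2%.

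Of the 44 genes that control cells switched on, most were lower in unloaded cells at day 3. After 7 days of unloading 33 were lower than in control cells, 5 were higher and 6 did not pass the test, with a median log2 difference of -3.63. After 14 days 33 were lower, 8 were higher and 3 did not pass, with a median of -6.01; 9 were at the floor. Direct comparison of the unloaded groups at day 3 found 28 of the 44 lower after 14 than after 7 days and 7 higher. At day 0, before induction, 10 of the 44 were lower than in control cells after 7 days and 7 higher, and 12 were lower and 7 higher after 14 days. For 21 and 24 of them a group compared was at or under the floor at day 0, so that their day 0 levels could not be compared at this depth. The median of the 44 moved to -3.02 and -4.01 with the filter of at least 1 CPM in at least 4 libraries. That filter removes genes that reach 1 CPM in fewer than 4 libraries, and it left 32 genes, 21 of them lower after 14 days. These genes were chosen with the control libraries that they were then compared with.

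The 33 genes that were lower after 14 days took 0.580% ± 0.00304 of the counts of control cells at day 3, 0.0678% ± 0.00205 after 7 days and 0.0295% ± 0.000391 after 14 days (SD, n = 2). Their median gene stood at 26.1 ± 1.11, 2.38 ± 0.140 and 0.658 ± 0.0264 CPM in these groups. ENSRNOG00000028616 reached 5.50 ± 0.619 CPM after 7 days and 0.658 ± 0.0264 CPM after 14 days, against 131 ± 6.71 in control cells (log2 difference -4.58, SE 0.13, and -7.63, SE 0.18; adjusted p = 2.73e-24 and 7.37e-27). The other 11 genes took 0.475% ± 0.00270 of the counts in control cells, 0.781% ± 0.0343 after 7 days and 0.685% ± 0.0169 after 14 days, and 8 of them were higher than in control cells after 14 days. The split into 33 and 11 was made on the 14-day libraries at day 3, so the size of their difference there is not independent of the choice.

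**Figure D2:**
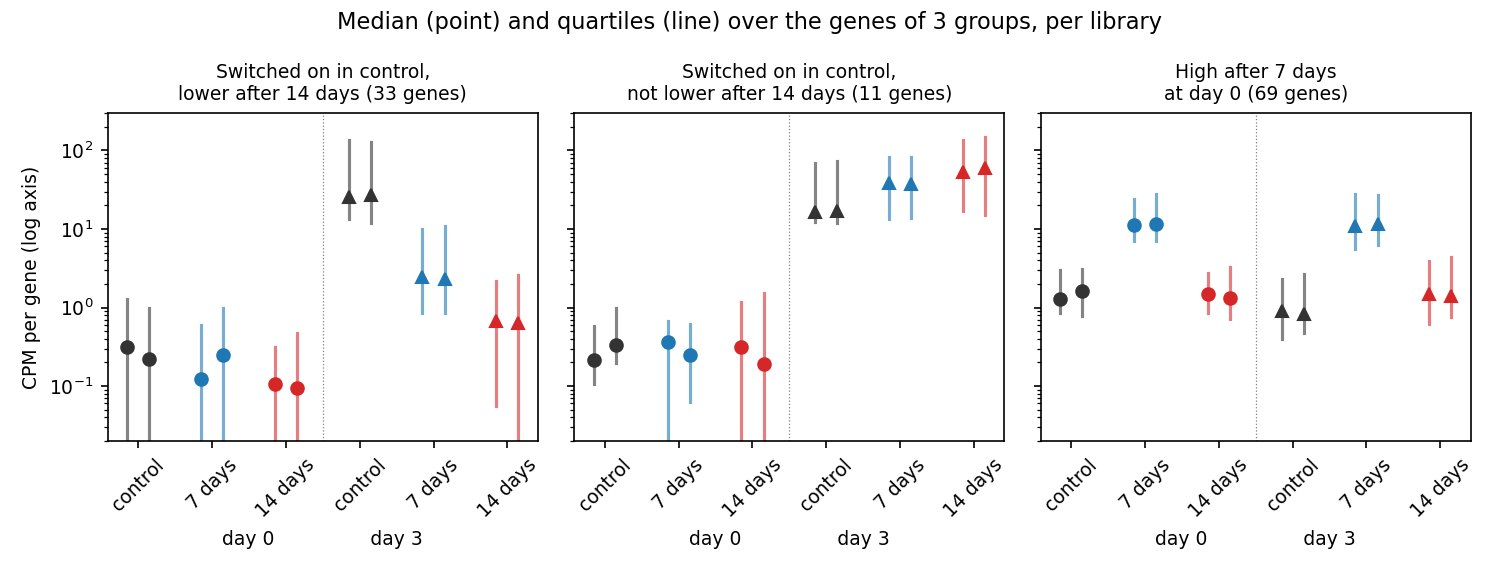
CPM per gene (log axis) in each of the 12 libraries for the 33 genes switched on in control cells and lower after 14 days of unloading, the other 11 switched-on genes and the 69 genes high after 7 days at day 0: points are medians over genes, lines run from the lower to the upper quartile, and a quartile of 0 is drawn at the lower end of the axis. At day 3 the median of the 33 genes falls from control to 7 days to 14 days, and the median of the 69 genes stands high in the 7-day libraries at both days.

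Most genes switched on in one treatment also rose in the others. Of the 44 genes of control cells, 41 rose in 7-day cells (median 24.6-fold over the 44) and 28 in 14-day cells (8.29-fold). By the same selection 24 genes were switched on in 7-day cells, all 24 of which rose in control cells, and 31 in 14-day cells, 30 of which rose in control cells (median 17.8-fold over the 31). At the 32-fold limit control and 7-day cells shared 19 genes, control and 14-day cells 13, 7-day and 14-day cells 17, and 13 were switched on in all 3. The 31 genes, chosen on the 14-day libraries, were lower than in control cells at day 0 in 16 cases and higher in 7, and at day 3 higher in 21 and lower in 3.

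The next comparison asked how cells of unloaded rats differed from control cells before induction. After 7 days of unloading 1546 genes were higher and 1496 lower than in control cells at day 0, and 340 and 206 of these differed at least 2-fold. After 14 days 1038 were higher and 1175 lower, 146 and 288 at least 2-fold. A group of 69 genes stood at least 4-fold above control after 7 days, with a median log2 difference of 3.29, and took 0.202% ± 0.00245 of the counts there against 0.0199% ± 0.00125 in control cells (SD, n = 2). After 14 days the share was 0.0223% ± 0.0000912 and the median log2 difference from control -0.21, with 6 genes higher, 6 lower and 57 not past the threshold. In the direct comparison, 67 of the 69 were lower after 14 than after 7 days at day 0. The 69 genes were chosen on these same 7-day libraries, so the choice bears on this count. With scaling to the total count, 62.8% of the genes changed after 7 days were higher, against 50.8% with TMM, and 38.1% of those changed after 14 days, against 46.9%.

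After 14 days 41 genes were at least 4-fold below control, with a median log2 difference of -2.46, and 40 of them were also lower after 7 days, where their median was -1.67. After 7 days 16 genes were at least 4-fold below control, and all 16 were also lower after 14 days. In the direct comparison of 14 with 7 days, 31 of the 41 genes chosen on the 14-day libraries were lower after 14 days, but of the 16 chosen on the 7-day libraries 6 were lower, 1 was higher and 9 did not pass the test, so the choice of genes bears on this count. Only 7 genes were at least 4-fold above control after 14 days, 6 of which were also higher after 7 days. The comparisons share the control libraries, and real differences of the control cultures from all others would lower both groups alike, so the number of genes low in both does not show an effect common to both periods.

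After 3 days of induction the 14-day cells differed from control cells in more genes than the 7-day cells did. At day 3, 892 genes were higher and 982 lower after 7 days of unloading, 269 and 252 at least 2-fold, and 2116 were higher and 2016 lower after 14 days, 243 and 383 at least 2-fold. ENSRNOG00000013973 had the largest fitted rise after 14 days: 178 ± 0.690 CPM against 17.3 ± 2.22 in control cells (SD, n = 2; log2 difference 3.37, SE 0.10, adjusted p = 4.58e-26), with 122 ± 6.60 CPM after 7 days. Its day 0 levels already differed: 1.24 ± 0.497 CPM in control cells, 3.68 ± 0.631 after 7 days and 2.12 ± 0.156 after 14 days. Both unloaded groups were higher than control cells then (adjusted p = 7.71e-06 and 0.0481). ENSRNOG00000009686 had the largest fitted fall, from 24.2 ± 1.48 CPM in control cells to 0 reads after 14 days, at least 295-fold lower, or 147-fold if reads were counted in pairs (adjusted p = 2.33e-16), and stood at 1.05 ± 0.722 CPM after 7 days. Scaling to the total count shifted the median gene of the 14-day comparison by -0.11 on the log2 scale, and 30.2% of its changed genes were then higher, against 51.2% with TMM.

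**Figure D3:**
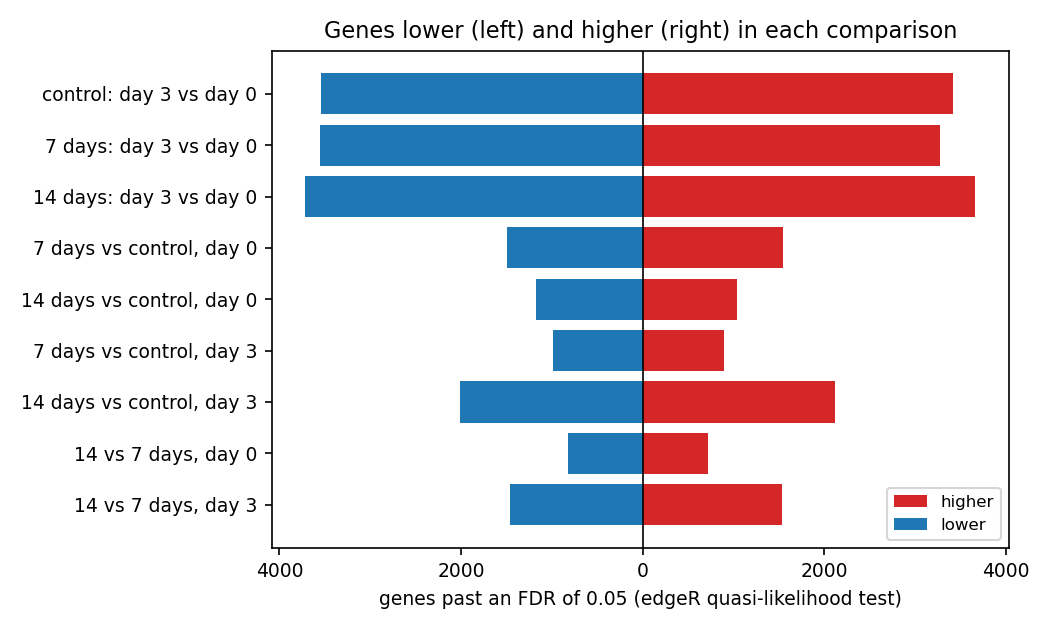
Number of genes past an FDR of 0.05 in each of the 9 comparisons (horizontal axis, genes; edgeR quasi-likelihood test), red bars to the right for genes higher in the group named first and blue bars to the left for genes lower in it. The most genes differed between day 3 and day 0 (6960 in control cells), and 4132 differed between 14 days of unloading and control at day 3.

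Differences present before induction were in part still there at day 3. Over genes, the log2 differences from control at day 0 and at day 3, which share no library, correlated at r = 0.43 (Spearman 0.29) for 7-day cells and at 0.19 (0.12) for 14-day cells. For 7-day cells 447 genes were higher at both days, 393 lower at both and 108 changed sign, against 104, 111 and 216 for independent lists. For 14-day cells these numbers were 439, 375 and 382, against 166, 179 and 346. Of the 69 genes high after 7 days at day 0, 67 were also higher than control at day 3, in libraries not used to choose them, with a median log2 difference of 3.72. After 14 days 23 of the 69 were higher than control at day 3, with a median of 0.64, and 65 were lower than after 7 days.

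The last comparisons set the unloading periods against each other. Between 14 and 7 days, 723 genes were higher and 827 lower at day 0, of which 42 and 274 differed at least 2-fold. At day 3, 1529 were higher and 1459 lower, 89 and 322 at least 2-fold. The day 0 total of 1550 fell to 862 without the first and 887 without the second 14-day library at day 0, and the day 3 total of 2988 to 1848 without the first 7-day and 1700 without the first 14-day library at day 3. With scaling to the total count, which moved the median gene by up to 0.113 on the log2 scale, 20.6% of the changed genes were higher at day 0, against 46.6% with TMM, and 22.1% at day 3, against 51.2%.

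The 7-day and 14-day changes from control overlapped at both days. In fits of the 6 libraries of a day, 1220 genes passed the threshold in both comparisons with the same sign at day 0, 517 higher and 703 lower, and 29 with opposite signs. Independent lists of these sizes would share 101 higher, 111 lower and 213 opposite. At day 3 there were 687 higher, 765 lower and 79 opposite, against 186, 190 and 376. The correlation over genes was 0.52 at day 0 and 0.64 at day 3, where 20 simulations of unchanged groups with the same controls gave means of 0.50 and 0.52 and at most 0.05 genes with the same sign on average. Covariances were 0.169 and 0.320, against 0.0235 and 0.0237 simulated, a difference of 0.146 and 0.297. Simulated groups with independent differences of their own, control included, also gave r = 0.50 at both days, with covariances 0.109 and 0.142 above those of unchanged groups. They changed more genes (6206 and 6239 at day 0) and shared 3166 with the same sign and 695 with opposite signs at day 0, and 3759 and 1008 at day 3. Some excess of shared signs can thus arise without a shared effect of unloading. Its size cannot be set beside the observed one, as these groups were given a spread that already held counting noise. Their highest r was 0.516 at day 0 and 0.512 at day 3, against 0.523 and 0.644 observed. Their highest covariance difference was 0.114 and 0.147, against 0.146 and 0.297 observed. Each simulated group was given the same spread, so a control group that differs more than the unloaded groups was not simulated. Observed values above the simulated ones therefore do not show a shared effect of unloading. The 2 control libraries of a day cannot be split, so part or all of the excess may come from them.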

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

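All tests of explanations in this part were chosen after the results had been seen. The results below stand here because the response to induction differed between unloaded and control cells, by the interaction test of edgeR. The response differed in 1371 genes after 7 days of unloading and in 2900 after 14 days. ENSRNOG00000013973 had a larger response after both 7 days (log2 difference of the responses 1.26, SE 0.30, adjusted p = 0.00316) and 14 days (2.61, SE 0.32, adjusted p = 6.74e-08). Of ENSRNOG00000009686 the response was smaller after 7 days (adjusted p = 0.0387), where both its day 0 groups had at most 2 reads. For 14 days both its day 0 groups had 0 reads, so a difference in its response could not be tested there. Among the 44 genes switched on in control cells, the response was smaller in 15 after 7 days and in 24 after 14 days, and larger in 1 and 4. Of the 44, 6 and 2 had 0 reads at day 0 in both groups compared, which leaves no ratio to test, and most others had few, so these numbers are limited by the depth at day 0.

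The first pattern is the lower day 3 level of genes that control cells switched on. Scaling is argued against, since it moved the median gene by at most 0.1134 on the log2 scale and the 33 lowered genes lay at a median of -3.86 after 7 days and -6.65 after 14 days. Fewer cells in the switched-on state would lower genes silent at day 0 by a single ratio; beyond noise the ratios spread by 0.4272 log2 after 7 days (95% bootstrap interval 0.254 to 0.534, 14 of the 33 genes) and 0.6735 after 14 days (0.0765 to 0.923, 7 genes), too few genes to decide. The length of unloading stays open as a biological explanation, as 27 of the 33 genes were lower after 14 than after 7 days in a set chosen on the 14-day libraries. Differences between cell isolations cannot be told apart from unloading, because each group has 2 libraries and no label of the isolation they came from.

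The second pattern is the 69 genes that stood high after 7 days of unloading at day 0, 67 of them also at day 3, and far less so after 14 days. Scaling is argued against here too, with its largest shift of 0.1134. An effect of unloading still present after 14 days is argued against at day 0 by a median log2 difference from control of -0.2106, but stays open at day 3, where the median was 0.6396 with 23 genes higher and 0 lower. A larger share of cells of another type may account for the pattern, since the median of 3.717 at day 3 shows that the difference outlasted induction, but a lasting change of expression within the cells would give the same value, and without gene names no marker could be looked at. An effect that is smaller after 14 than after 7 days, and differences between isolations (2 libraries per group, none with a named isolation), cannot be told apart by the design.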

How the results depend on the processing

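Over 25 settings, 765 alternative values were computed. Of these, 692 kept their direction and threshold or moved within the limits set for them, and 73 moved beyond them. Most of the 765 are counts of genes, which have no direction to lose. Most of the 73 are correlations of the responses, each of which stayed within its limits in 4 of 22 alternatives. Of the 765 values, the fold changes of the 4 named genes carry an adjusted p of their own. These stayed past the threshold wherever they were computed (largest adjusted p = 0.000404). ENSRNOG00000009686 was removed by the filter of at least 1 CPM in at least 4 libraries and has no value there. Halved counts, total-count scaling and the rebuilt gene groups were chosen after the data had been seen. The tests of the 34 gene lists and the run without mitochondrially encoded genes were not run for want of gene names. The depth limits genes at 0 to 3 counts in a group, and where a library was left out, the lone library of its group was assumed to vary like the others.

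The correlations of the responses (control with 7 days, control with 14 days, 7 with 14 days) were 0.488, 0.468 and 0.508 with DESeq2, 0.418, 0.410 and 0.442 with no filter, 0.805, 0.738 and 0.834 with voom, 0.860, 0.798 and 0.883 with at least 1 CPM in at least 4 libraries, 0.906, 0.826 and 0.924 for genes with a mean of at least 10 CPM, and 0.842, 0.761 and 0.861 with halved counts. DESeq2 and no filter took in 18827 genes, halved counts 12318 and the stricter filter 12071, so more genes of low count enter where r is low; for voom, with the same genes, the cause was not tested. Leaving out each library in turn gave 0.713 to 0.759, 0.648 to 0.694 and 0.732 to 0.777, all below the values from all libraries. Those fits kept 13586 to 13623 genes, against 13215 with all libraries, and whether the added genes lowered r was not tested.

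Leaving out each library in turn gave 862 to 1695 changed genes between 14 and 7 days at day 0, 1700 to 3351 at day 3, and 790 to 1410 genes with the same sign in the overlap at day 0. It gave a median log2 difference at day 3 of -3.71 to -3.50 after 7 days and -6.21 to -5.41 after 14 days for the genes switched on in control cells, and of 3.61 to 3.75 for the genes high after 7 days. With at least 1 CPM in at least 4 libraries the medians of the switched-on genes were -3.02 and -4.01 and the number lower after 14 days 21, by construction, since that filter removes genes that reach 1 CPM in fewer than 4 libraries. With halved counts the 14-day median was -5.50, and the cause was not tested.

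No pairing of the libraries by replicate number was seen over all genes: deviations of same-numbered libraries from their group means correlated between -0.051 and 0.041 over the 15 pairs of groups. Noise in genes of low count could hide a weak pairing, so it is not excluded. With the replicate number as a block, 6856 genes changed from day 0 to day 3 in control cells, against 6960 without it, and 4005 after 14 days of unloading at day 3, against 4132; blocks within treatment gave 6888 in control cells. No count of changed genes moved by over 1.5 times under a block.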

Other observations

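All tests in this part were chosen after the data had been seen. The hypothesis that unloading moved the cells as a whole along the response to induction was tested by correlating, over 13215 genes, the differences from control with the response of the other unloaded cells, which share no library. At day 0 the correlation was -0.01659 (Spearman -0.022) for 7-day cells and -0.09179 (-0.101) for 14-day cells. At day 3 it was 0.02243 (0.115) and -0.05273 (0.056), so the sign for 14-day cells depended on the measure. These small values argue against such a shift of all genes as a main part of the differences.

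Even counts outnumber odd ones in every library. A candidate explanation is that both reads of a pair were counted, since the variance between replicates over genes with 20 to 99 reads was 2.192 times that of single reads (median of 6 groups, range 2.13 to 2.34). Replicates that differ for other reasons also raise this value.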
